A study of Mus musculus with 28 samples.

How the data were processed

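The samples were 28 RNA-seq libraries of mouse CD4 T cells from the C57BL/6 strain, taken from the spleen. Per the labels' protocols, naive CD4 cells were sorted, activated with plate-bound anti-CD3 and anti-CD28 at 1 µg/ml each, and cultured toward non-pathogenic Th17 cells (Th17n; IL-6 at 25 ng/ml and TGF-beta 1 at 2 ng/ml) or induced regulatory T cells (iTreg; TGF-beta 1 at 2 ng/ml). Cultures were kept with or without 100 µM DFMO, an inhibitor of ornithine decarboxylase, harvested at 68 h and sorted for live cells. Full-length libraries were sequenced as paired reads of 75 bp. Cells came from 4 wild-type (WT) animals and from 3 animals in which the floxed JMJD3 gene (Kdm6b) was deleted in T cells by CD4cre (KO). Each animal gave 4 libraries, 1 per differentiation and treatment, so 8 groups of 3 or 4 libraries resulted. Untreated cultures are called ctrl.

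The authors deposited 2 kinds of value for 20891 genes, an estimated count per gene and a TPM. Both came from kallisto with the GRCm38 build, per the submitters' processing notes; the kallisto version was not given in the sources used here. Of the deposited estimated counts, 67.2% were whole numbers within 0.001, the rest being fractions that kallisto assigned to genes. The deposited TPM of each library summed to 863920 to 886579. All 20891 gene names matched GENCODE M21, which gave the positions and the GC content. Gene-level values do not separate exons, so the deleted part of Kdm6b was not resolved. Strand was not used, so overlapping and antisense genes cannot be told apart.

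Estimated counts were rounded to whole numbers and fitted in edgeR 4.0.16 (R 4.3.3) with 1 quasi-likelihood model of the 8 group means over all 28 libraries, without a block. That left 20 residual degrees of freedom, 9.24 prior degrees of freedom and a common dispersion of 0.0182. Libraries were scaled by TMM, and edgeR's filter on low counts kept 10985 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F. Levels are in CPM (the count scaled to library size) given as mean ± SD over libraries, and log2 CPM used a prior count of 2. There were 13 comparisons. These were DFMO against ctrl in each genotype and differentiation, KO against WT in each culture, Th17n against iTreg in each genotype's ctrl libraries, the interaction of DFMO with genotype in each differentiation, and the interaction of DFMO with differentiation in WT.

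Genes were named by a rule fixed, like the comparisons, gene lists and most alternatives, before the data were examined. Kdm6b, Odc1, Il17a, Il17f, Il23r and Foxp3 were always reported. Otherwise the 10 largest called changes each way were named (5 each way for interactions), given a mean of at least 10 CPM and, for comparisons of groups, the same direction in every animal or groups that did not overlap. From gene lists, up to 4 members of smallest adjusted p were named. Where few members of a list were called or moved against it, they were also named, outside the rule and after their values were seen. Genes without an approved symbol were counted only. A few genes that the rule names are not reported here. Fixed lists of 716 gene entries were written from general knowledge, of which 699 matched: 31 pathway lists and 12 cell type lists. The 30 pathway lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01), again with an estimated correlation, and with fry. Where the text gives 2 counts of list members, the second is adjusted over the list alone, and where it gives 1 the counts were equal.

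A DFMO response score per animal was the mean, over responsive genes, of the log2 CPM difference between DFMO and ctrl, signed by the direction of the effect. Responsive genes had an adjusted p under 0.05 in a limma fit of all animals' differences to 1 mean, blind to genotype, in each differentiation. Scores of KO and WT animals were compared with an exact two-sided permutation test over 35 splits, whose smallest possible p is 0.0286. Gene calls in the comparisons named next, camera with the preset correlation and the response score were tested on simulated counts with known changes over 10985 genes. The other steps were not. For DFMO in WT Th17n, 47.8%, 73.1% and 87.9% of genes changed 1.5-, 2- and 4-fold were recovered, with 8 false calls. For KO against WT in Th17n ctrl these shares were 34.3%, 77.6% and 93.9%, with 9 false calls. The DFMO by genotype interaction in Th17n recovered 11.9%, 47.8% and 81.8%, with 5 false calls. A simulated list of 20 genes raised 1.5-fold was called, and 0 of 30 unchanged lists were. These genes were simulated independently, so this does not test camera where list members are correlated. A simulated KO response of 50% of that in WT gave a score ratio of 55.1%. Genes that respond in 1 genotype only are less likely to be picked as responsive, and that case was not simulated. The score thus measures the size of the shared response and can miss such genes.

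Total estimated counts ran from 2226914 to 4759290 per library. Between replicates the counts varied more than counting error alone, with a chi-square per degree of freedom of at least 2.88. Where a group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% exact interval, and floors and intervals cover counting error only. The labels give each animal 4 libraries, so libraries in DFMO and differentiation comparisons pair by animal. The p-values are from the fit without the block, and the animal as a block was an alternative. Libraries of 1 animal in different cultures had a median correlation of deviations from the group means of 0.084 (-0.032 to 0.313, 42 pairs). For different animals of 1 genotype it was -0.023 (-0.227 to 0.091, 108 pairs). Alternatives were other size factors (RLE), no filter or a mean of at least 5 CPM, only the groups compared, the animal as a replicate block, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, and each library left out in turn. Corrections for GC content, leaving out both iTreg libraries of WT animal 4, an estimated correlation for the signature test and split ctrl libraries for the shared KO genes were added after the data were seen. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.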

Results

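Gene expression was measured in Th17n and iTreg cells of WT and JMJD3-deficient mice, with and without DFMO, to ask whether the effect of polyamine depletion on Th17 cells depends on the histone demethylase JMJD3. The 8 groups held 4 libraries each for WT and 3 each for KO. Total estimated counts per library were 4561014 to 4759290 in Th17n ctrl WT, 2226914 to 4143568 in Th17n ctrl KO, 3590879 to 4496220 in Th17n DFMO WT and 3957830 to 4732039 in Th17n DFMO KO. In iTreg they were 2792847 to 4753768 for ctrl WT, 2312481 to 2911716 for ctrl KO, 3233025 to 4066614 for DFMO WT and 3406287 to 4528484 for DFMO KO. The first principal component held 43.0% of the variance and the second 21.5%.

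**Figure D1:**
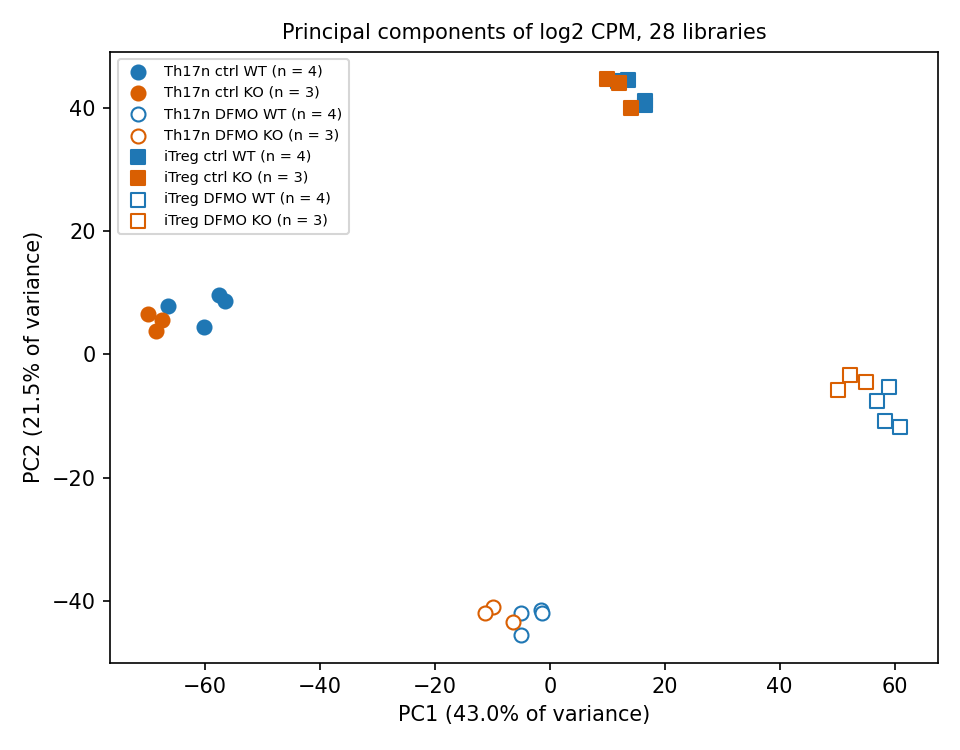
Each point is 1 of 28 libraries on the first and second principal components of log2 CPM (43.0% and 21.5% of the variance). Colour marks genotype, shape the differentiation, and open symbols DFMO.

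The targeted gene came first. Kdm6b (GRCm38 chromosome 11, 69398508 to 69413675, minus strand) was lower in KO means of all 4 cultures but was not lost. In Th17n it stood at 47.1 ± 11.5 CPM in WT (n = 4) and 34.1 ± 8.06 in KO (n = 3) without DFMO, where single libraries of the genotypes overlapped (33.5 to 60.6 against 28.7 to 43.4). With DFMO it stood at 54.4 ± 12.9 in WT and 28.02 ± 4.51 in KO, and groups did not overlap. In iTreg the means were 43.3 ± 4.64 and 31.2 ± 2.10 CPM without DFMO, and 49.1 ± 7.49 and 24.6 ± 4.13 with it. KO was lower by edgeR in the DFMO cultures, with log2 fold changes of -0.95 ± 0.19 in Th17n (adjusted p = 0.0076) and -1.01 ± 0.20 in iTreg (adjusted p = 0.00251). The ctrl differences of -0.44 ± 0.20 and -0.48 ± 0.20 did not pass. The Th17n DFMO call was lost without Th17n DFMO KO replicate 1 (-0.86), and neither DFMO call held on TPM (-0.32 and -0.39). Gene-level estimates include exons that the deletion leaves in place, so they check the genotype only in part.

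To evaluate polyamine depletion in WT Th17n cells, DFMO was set against ctrl. Expression of Foxp3, which specifies regulatory T cells, rose 3.83-fold (1.94 ± 0.22 log2, edgeR adjusted p = 2.47e-08, all 4 animals), from 9.65 ± 3.72 to 37.1 ± 5.52 CPM. Among Th17 genes, Il17a fell by 1.46 ± 0.37 (2.75-fold) and the IL-23 receptor gene Il23r by 1.52 ± 0.30. Il17f fell by 0.87 ± 0.30 (adjusted p = 0.0166 by edgeR), from 916 ± 328 to 502 ± 223 CPM. This call was lost without Th17n ctrl WT replicate 4 (-0.63), Th17n DFMO WT replicate 1 (-0.61) or replicate 3 (-0.75), with DESeq2 (-0.86) and on TPM (-0.90). Kdm6b was not called (0.21 ± 0.17) although it was higher in all 4 animals, and it was called without Th17n DFMO WT replicate 1 (0.40). Odc1, which encodes the enzyme DFMO inhibits, rose 1.57-fold, and the spermidine synthase gene Srm rose 9.30-fold, from 41.9 ± 7.79 to 390 ± 56.0 CPM.

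**Figure D2:**
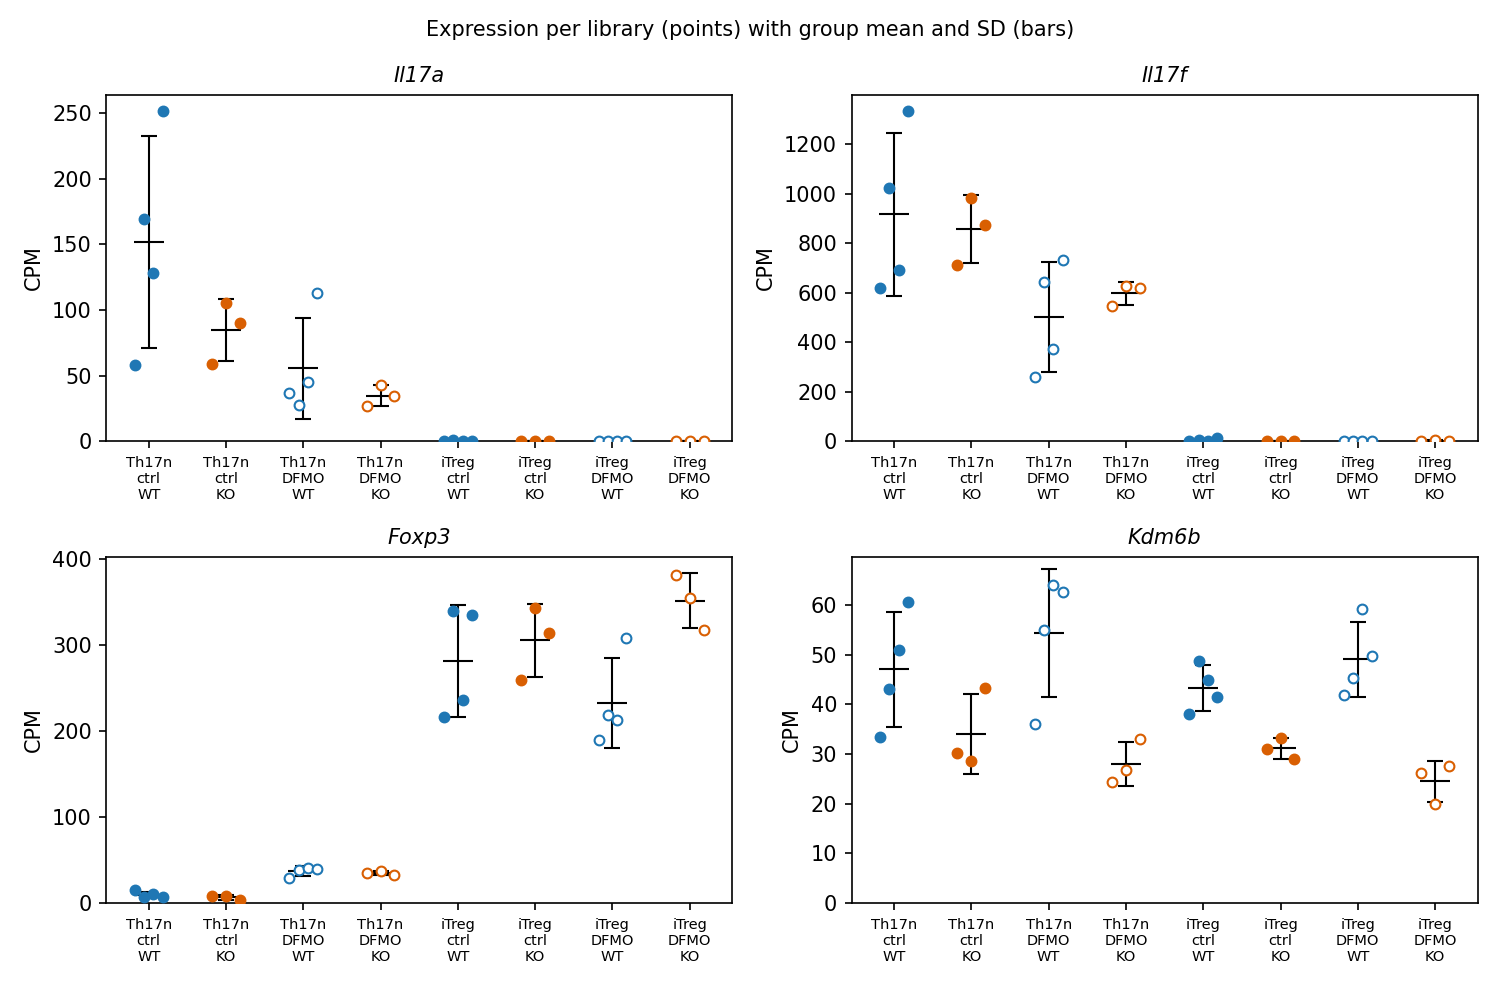
CPM of Il17a, Il17f, Foxp3 and Kdm6b in each library by group, with mean and SD. WT is blue and KO orange, and open symbols are DFMO. Foxp3 in Th17n lay at 9.65 CPM in WT ctrl and 37.1 CPM in WT DFMO.

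The largest rises in WT Th17n cells under DFMO included Tnfsf11 (the cytokine RANKL, 20.0-fold), Nrp1 (neuropilin 1, 11.9-fold) and the chemokine gene Ccl4 (8.28-fold). The largest falls included Tgfb3 (19.0-fold), Gipr (24.7-fold), complement C3 (13.7-fold) and Ly6g (112-fold). With DFMO the WT libraries held only 0 to 3 counts of Ly6g, so the size of its fold is uncertain. Ly6g and Ly6c1 belong to a family of close paralogs, so their shares of reads are uncertain. By edgeR, 2571 genes rose and 3119 fell of 10985 tested, 1779 of them at least 2-fold. More genes rose than fell on TPM (2343 and 2244), with no filter (2787 and 2734) and with only the groups compared (2928 and 2837). Each of the genes just named moved the same way in all 4 animals.

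Fixed gene lists were then tested. Of 31 DNA replication genes 29 rose and 0 fell (30 adjusted over the list alone), with 2 not called, among them Rrm2 (1.76 ± 0.09) and Cdc6 (1.78 ± 0.12). Of 30 ribosome biogenesis genes 28 rose, among them Nolc1 (1.61 ± 0.09) and Nop56 (1.47 ± 0.09), and Npm1 fell. Of 12 heat shock genes 8 rose, such as the chaperonin gene Hspd1 (1.00 ± 0.08). These 3 lists passed camera with the preset correlation (adjusted p = 3.96e-18, 2.95e-17 and 0.000898) and with an estimated one (adjusted p = 0.0201, 0.00571 and 0.0451).

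Another 9 lists passed camera only with the preset correlation. In glycolysis 15 of 21 fell (16 adjusted over the list alone), such as Aldoc (-3.40 ± 0.15) and the glucose transporter Slc2a3 (-2.24 ± 0.20), with Slc16a1 alone higher (adjusted p = 0.235 with an estimated correlation). In fatty acid oxidation 13 of 19 fell, Hadh and Acadl among them, and Etfa and Etfb rose (adjusted p = 0.196 with an estimated correlation). In oxidative phosphorylation 23 of 34 rose, such as Ndufa4 (0.88 ± 0.09), while Ndufs3 and Uqcrc2 fell (23 and 3 adjusted over the list alone, adjusted p = 0.294 with an estimated correlation). In ER chaperones 12 of 18 rose, among them Dnajb11 and Hspa5 (BiP), and Sel1l fell (adjusted p = 0.148 with an estimated correlation). In G2 and M phase genes 12 of 25 rose and 0 fell, such as Birc5 and Cdk1 (adjusted p = 0.386 with an estimated correlation). In the immediate early list 9 of 20 rose, such as Ier2 and Dusp2, and Fosl2, Irf4 and Tnfaip3 fell (adjusted p = 0.196 with an estimated correlation).

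The last 3 of these 9 lists were lower. In the IL-6 and STAT3 response 9 of 19 fell, such as Pim2 (-1.99 ± 0.13) and Socs3 (-1.17 ± 0.09), and Il21 rose (adjusted p = 0.200 with an estimated correlation). In the Th17 programme 11 of 19 fell, such as Stat3 (-0.86 ± 0.08) and Hif1a (-1.27 ± 0.14), and Ccl20 (2.17 ± 0.27) and Il21 rose (adjusted p = 0.25 with an estimated correlation). In naive and memory T cell genes 7 of 13 fell, such as Satb1 and Ccr7, and Id3 rose (adjusted p = 0.200 with an estimated correlation). With the animal as a block, 2 more lists passed as lower, the Th1 programme (camera adjusted p = 0.0379, against 0.0516) and the Treg programme (0.0442, against 0.0979). Neither passed with an estimated correlation (camera adjusted p = 0.25 and 0.386). In the Treg programme Tnfrsf9 (-3.13 ± 0.14) and Tnfrsf18 (GITR) fell although Foxp3 and Nrp1 rose. The other lists did not pass, with camera adjusted p from 0.0556 to 0.814. They were polyamine metabolism, JmjC demethylases, H3K27 methylation, interferon-stimulated genes, ATF4 stress response, p53 targets, cholesterol synthesis, serine and one-carbon metabolism, TCA cycle, the mitochondrial genome, TGF-beta response, chemokines, Tfh and Th2 programmes, and pathogenic and non-pathogenic Th17 genes. Of 19 polyamine genes 12 rose and 5 fell (13 and 5 adjusted over the list alone), with Oaz2 (-1.81 ± 0.16) and the spermidine acetyltransferase Sat1 (-0.69 ± 0.08) lower.

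To see whether these effects needed JMJD3, the same comparison was made in KO Th17n cells (n = 3). Foxp3 rose 5.48-fold (2.45 ± 0.31, edgeR adjusted p = 1.53e-07, all 3 animals), Srm 5.42-fold and Il2, the T cell growth factor, 9-fold. Gipr fell 31.4-fold, C3 14.7-fold and Tgfb3 9.04-fold. Gdpd2, a phosphodiesterase gene, held 232 counts in ctrl and 1 with DFMO (ratio 355, interval 63.0 to 14100). Il17a fell by 1.30 ± 0.45 (adjusted p = 0.0207 by edgeR), but not with DESeq2 (-1.29) or without Th17n ctrl KO replicate 2 (-1.13) or 3 (-1.25), or Th17n DFMO KO replicate 1 (-1.12) or 3 (-1.30). Il17f (-0.52 ± 0.35) and Il23r (-0.84 ± 0.37) were not called. Il17f was called with the animal as a block (-0.51, edgeR adjusted p = 0.0265), with no filter (-0.43) and with only the groups compared (-0.46), and Il23r on TPM (-0.52). Odc1 rose by 0.41 ± 0.16, a call lost without Th17n ctrl KO replicate 1 (0.37) or 2 (0.36) or Th17n DFMO KO replicate 2 (0.43) or 3 (0.28), on TPM (0.38) and with the GC correction without the block (0.40). Kdm6b was not called (-0.31 ± 0.21).

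In KO Th17n cells 2314 genes rose and 2699 fell by edgeR. The balance turned on TPM (2164 and 1972), with only the groups compared (2752 and 2626) and with no filter (2585 and 2288). Of 31 DNA replication genes 30 rose, of 30 ribosome biogenesis genes 28, and of 12 heat shock genes 8, and these lists held with an estimated correlation (camera adjusted p = 0.0078, 0.00446 and 0.0399). Another 9 lists passed camera with the preset correlation only (adjusted p = 0.162 to 0.462 with an estimated correlation). Among them 15 of 21 glycolysis genes fell and 22 of 34 oxidative phosphorylation genes rose (16 and 23 adjusted over the list alone), 10 of 20 JmjC demethylase genes fell and 13 of 21 Treg programme genes fell. The block added serine and one-carbon metabolism (camera adjusted p = 0.0245, against 0.0573), the Th1 programme (0.0324, against 0.0573) and the Th17 programme (0.0467, against 0.0676), and 0 of these 3 passed with an estimated correlation (0.262 to 0.281). Of the genes called in WT and in KO, 4281 in number (2596.6 for independent lists), 4274 moved the same way.

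**Figure D3:**
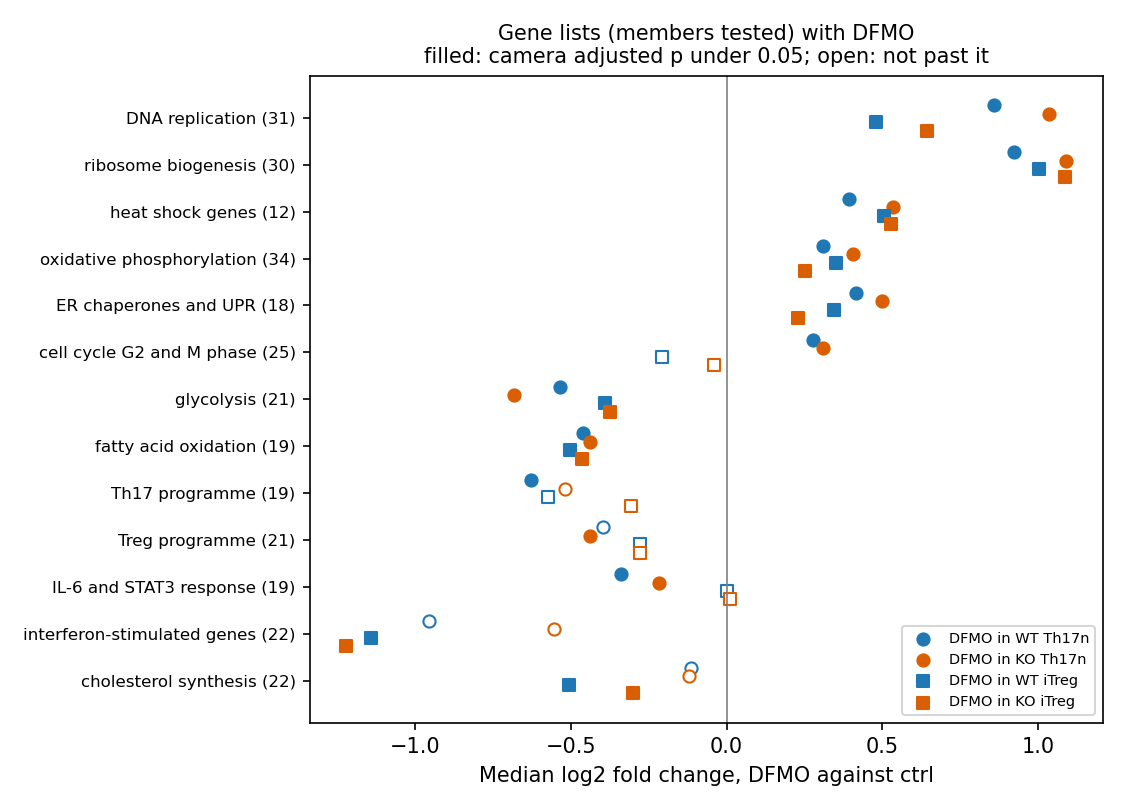
Median log2 fold change of 13 gene lists under DFMO, for WT and KO in Th17n and iTreg. Filled symbols passed camera with the preset correlation at an adjusted p under 0.05.

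To test directly whether DFMO acted differently in KO Th17n cells, the interaction with genotype was fitted. DFMO lowered Ly6g less in KO (4.29 ± 0.63, adjusted p = 0.00221 by edgeR), from 104 ± 28.9 to 17.9 ± 6.71 CPM, against 46.1 ± 14.8 to 0.372 ± 0.327 in WT. Plac8 (2.46 ± 0.42), Olfr1033 (0.97 ± 0.20) and Hmgn2 (0.49 ± 0.11) were also higher, but leaving out 1 library lost the call of Olfr1033 in 6 of 14 fits and that of Hmgn2 in 10. The DFMO effect was lower in KO for Rnf187, a ubiquitin ligase gene (-2.39 ± 0.40), and likewise for the phosphatase gene Dusp2 (-2.19 ± 0.38), Kctd13 (-2.06 ± 0.32), Plbd2 (-1.77 ± 0.24) and the immediate early gene Ier2 (-1.27 ± 0.25). For Rnf187 the genotypes differed mainly in ctrl libraries, at 29.8 ± 0.488 CPM in WT and 170 ± 20.8 in KO. With DFMO it stood at 363 ± 6.82 in WT and 394 ± 10.9 in KO. Th17 genes did not pass: Il17a differed by 0.15 ± 0.58, Il17f by 0.35 ± 0.46, Il23r by 0.68 ± 0.48, and Foxp3 by 0.52 ± 0.41. Kdm6b (-0.52 ± 0.27) and Odc1 (-0.24 ± 0.21) were not called either.

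The interaction in Th17n called 4 genes higher and 32 lower by edgeR, with 753 at an unadjusted p under 0.05. On TPM the split was 2 and 6, and with a GC correction and the animal as a block it was 15 and 47. The block alone called 57 genes. Without Th17n ctrl KO replicate 3 the count was 19, and without Th17n DFMO KO replicate 1 it was 21. DNA replication and the mitochondrial genome passed camera as higher, each with 0 members called by edgeR (adjusted p = 0.708 with an estimated correlation for both). The block added naive and memory genes and oxidative phosphorylation (camera adjusted p = 0.0345 for both, against 0.0714), and the Treg programme as lower (0.0438, against 0.0973), and 0 of these 3 passed with an estimated correlation (0.708 to 0.771). Over 7004 responsive genes the response score was 0.766 ± 0.028 in WT animals (n = 4) and 0.783 ± 0.028 in KO animals (n = 3), a ratio of 102.2% (exact permutation p = 0.429).

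KO and WT were compared in untreated Th17n cells next. Dusp2 was 5.82-fold higher in KO (2.54 ± 0.29, edgeR adjusted p = 3.37e-06), Rnf187 5.70-fold, the adhesion gene Cdh17 3.40-fold and Ier2 2.37-fold. Tox, a transcription factor of T cells, was lower in KO (-1.29 ± 0.24), as were Timd2 (-1.36 ± 0.23) and the inhibitory receptor Ctla4 (-0.70 ± 0.13). Il17a (-0.83 ± 0.40), Il17f (-0.10 ± 0.32), Il23r (-0.65 ± 0.32), Foxp3 (-0.61 ± 0.35) and Odc1 (0.29 ± 0.15) were not called, except Il17a with no filter (-0.85). KO libraries had 252 genes higher and 82 lower by edgeR, and 146 and 86 on TPM. The count of 334 fell to 133 without Th17n ctrl KO replicate 3, 173 without replicate 1, 217 without replicate 2 and 218 without Th17n ctrl WT replicate 3. In all 8 lists passed camera (adjusted p = 1.44e-05 to 0.0493) and 0 held with an estimated correlation (adjusted p = 0.626 for the mitochondrial genome, lower in KO). In these lists edgeR called at most 2 members each (3 adjusted over the list alone), such as the nucleolar gene Fbl (1.10), which was higher although its list was lower.

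Under DFMO, 112 genes separated the genotypes in Th17n, 42 of them also called in ctrl libraries. Ecm1, which encodes a matrix protein, was 4.23-fold higher in KO (2.08 ± 0.24, edgeR adjusted p = 6.16e-06), Tgfb3 3.79-fold, Plac8 3.72-fold and the lymphocyte receptor Slamf6 2.76-fold. The adhesion receptor Cd44 (-1.19 ± 0.17) and the stress regulator Atf3 (-1.01 ± 0.15) were lower in KO. Il17a (-0.67 ± 0.42), Il17f (0.25 ± 0.32), Il23r (0.02 ± 0.35), Foxp3 (-0.09 ± 0.21) and Odc1 (0.055 ± 0.145) were not called. KO had 71 genes higher and 41 lower by edgeR. Leaving out Th17n DFMO KO replicate 1 left 28, WT replicate 1 59, KO replicate 3 62, WT replicate 3 64 and KO replicate 2 70. Here 4 lists passed camera, and 0 held with an estimated correlation (adjusted p = 0.503 for each). They were ATF4 stress response (Chac1 lower), p53 targets (Cdkn1a and Plk2 lower), the Treg programme (Ctla4, Ikzf2 and Gpr83 lower, and 5 lower and 1 higher adjusted over the list alone) and DNA replication (higher, 0 members called). Without Th17n DFMO KO replicate 1 the calls of Chac1 (-0.66), Cdkn1a (-0.43), Ctla4 (-0.66), Ikzf2 (-1.42) and Gpr83 (-0.59) were lost. Without KO replicate 3 those of Chac1 (-0.64), Cdkn1a (-0.45) and Gpr83 (-0.47) were lost, Gpr83 also without WT replicate 3 (-0.52), and Chac1 without KO replicate 2 (-0.52) or WT replicate 1 (-0.55), 3 (-0.55) or 4 (-0.66).

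In WT iTreg cells DFMO raised the cytokine gene Il9 20.8-fold (4.38 ± 0.38, edgeR adjusted p = 2.14e-10), Srm 8.33-fold, Tnfsf11 7.62-fold and Dusp2 7.18-fold, each in all 4 animals. The chemokine gene Ccl22 held 2 counts in ctrl and 771 with DFMO (ratio 454, interval 125 to 3750). Aldoc fell 17.3-fold, Tgm2 (a transglutaminase gene) 11.7-fold and the MHC class II gene H2-Ab1 9.45-fold. Ctla4 fell by 2.09 ± 0.13. Foxp3 was not called (-0.28 ± 0.16), from 282 ± 64.8 to 232 ± 52.3 CPM, but it was called without iTreg DFMO WT replicate 4 (-0.45) and with the GC correction and block (-0.34). Odc1 was not called (0.30 ± 0.14), except without iTreg ctrl WT replicate 2 (0.40), iTreg DFMO WT replicate 4 (0.36) or both iTreg libraries of WT animal 4 (0.41), and with no filter (0.31). Il17f was not called (-2.29 ± 1.05), but it was with the animal as a block (-2.24, edgeR adjusted p = 0.0105), with no filter (-2.28), with DESeq2 (-2.39), with the GC correction and block (-2.23) and without iTreg ctrl WT replicate 1 (-2.73) or 3 (-2.62). Kdm6b was not called (0.17 ± 0.17). Il17a and Il23r had iTreg group means of at most 0.247 and 0.274 CPM, and neither was called in any comparison within iTreg.

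DFMO raised 2540 genes and lowered 2674 in WT iTreg cells by edgeR, but on TPM 1286 rose and 3191 fell. The median of all genes was -0.20 on TPM and -0.05 by edgeR, and the cause was not tested. Of 30 ribosome biogenesis genes 28 rose, and of 12 heat shock genes 9, and these lists held with an estimated correlation (camera adjusted p = 0.0102 and 0.0317). In 8 other lists the preset correlation alone gave a call (adjusted p = 0.129 to 0.472 with an estimated correlation). Among these, 27 of 31 DNA replication genes rose and 14 of 22 cholesterol synthesis genes, 14 of 21 glycolysis genes and 12 of 22 interferon-stimulated genes fell.

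In KO iTreg cells DFMO raised Ccl22 61.5-fold (5.94 ± 0.75, edgeR adjusted p = 5.69e-07), Il9 12-fold, the kinase gene Sgk1 6.29-fold and Srm 5.61-fold, in all 3 animals. The chemokine gene Ccl5 fell 19.3-fold, Tgm2 11.3-fold and Aldoc 9.42-fold. Foxp3 (0.20 ± 0.18), Odc1 (0.35 ± 0.17), Il17f (0.85 ± 1.63) and Kdm6b (-0.35 ± 0.23) were not called, except Odc1 with no filter (0.38) and with only the groups compared (0.35). By edgeR 2083 genes rose and 2098 fell, and on TPM 1328 and 2064. Of 30 ribosome biogenesis genes 27 rose (28 adjusted over the list alone), and of 12 heat shock genes 10 rose and Bag3 fell (camera adjusted p = 0.00253 and 0.00881 with an estimated correlation). Another 11 lists passed with the preset correlation only (adjusted p = 0.0586 to 0.537 with an estimated correlation), among them interferon-stimulated genes, of which 15 of 22 fell.

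Whether the iTreg response depended on genotype was tested in the same way. The DFMO effect on Sgk1 was higher in KO (1.57 ± 0.26, edgeR adjusted p = 0.00294), as it was for the interferon-gamma receptor gene Ifngr1 (1.09 ± 0.16) and Tspan9 (2.91 ± 0.57). Tspan9 lay outside the naming rule and was picked after its value was seen. Rnf187 (-2.30 ± 0.40), Kctd13 (-1.69 ± 0.32), Rps2 (-1.63 ± 0.27), Plbd2 (-1.54 ± 0.27) and B3gnt2 (-1.51 ± 0.25) had lower DFMO effects in KO, and Rps2 has many pseudogenes that can share its reads. With only the groups compared edgeR called 4 genes, and of those named here Ifngr1 alone kept its call. Foxp3 (0.48 ± 0.24), Kdm6b (-0.53 ± 0.29), Il17f (3.14 ± 1.96) and Odc1 (0.05 ± 0.22) were not called. By edgeR 3 genes were higher and 24 lower, with 1080 at an unadjusted p under 0.05. The splits were 11 and 8 on TPM and 18 and 52 with a GC correction and the block, and the block alone called 57 genes. Without iTreg DFMO WT replicate 4 edgeR called 99 genes, without iTreg ctrl WT replicate 2 67, without iTreg DFMO WT replicate 2 46, without iTreg ctrl WT replicate 4 41, without iTreg ctrl KO replicate 3 17 and without iTreg DFMO WT replicate 3 16. Camera called 10 lists and 0 held with an estimated correlation (adjusted p = 0.318 to 0.652). In these only Chac1 (lost without iTreg ctrl KO replicate 3, -1.07) and Ier2 (lost without iTreg DFMO KO replicate 2, -1.22) were called (2 and 3 lower in their lists adjusted over the list alone), and on TPM the medians of the ATF4 (0.12) and immediate early (0.00) lists lost their lower sign. Over 6069 genes the response score was 0.760 ± 0.039 in WT and 0.719 ± 0.038 in KO, a ratio of 94.6% (exact permutation p = 0.229).

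KO and WT were then compared in untreated iTreg cells. Granzyme B (Gzmb) was 16.9-fold lower (-4.08 ± 0.55, edgeR adjusted p = 2.18e-05), the carbonic anhydrase gene Car2 8.57-fold, the transcription factor gene Ikzf2 (Helios) 4.47-fold and Ly6a, which has close paralogs, 22.3-fold. Rnf187 was 6.72-fold higher, the TGF-beta co-receptor gene Eng 4.13-fold and Ccl5 3.82-fold. Tbx21 (T-bet, the Th1 regulator) was lower at 5.87 against 31.4 ± 15.7 CPM (-2.42 ± 0.64), though WT replicate 4 lay at 8.71, near KO replicate 3 at 8.03. That call was lost without any 1 of iTreg ctrl WT replicate 1 (-2.33) or 3 (-2.22) and iTreg ctrl KO replicate 1 (-2.31), 2 (-2.27) or 3 (-2.72). Of 14 Th1 programme genes 6 were lower, among them Gzmb and Il12rb2, and Ccl5 was higher (10 lower and 1 higher adjusted over the list alone), with a camera adjusted p of 2.28e-06 and 0.0212 with an estimated correlation. Another 6 lists passed with the preset correlation only (adjusted p = 0.0676 to 0.772 with an estimated correlation), among them ribosome biogenesis, with Nop58 and 4 others lower and Fbl higher (18 lower and 1 higher adjusted over the list alone). Foxp3 (0.12 ± 0.17), Il17f (-2.31 ± 1.25) and Odc1 (-0.07 ± 0.16) were not called, except Il17f with no filter (-2.33). KO had 348 genes higher and 234 lower by edgeR, and 199 and 229 on TPM. The count of 582 was 280 without iTreg ctrl KO replicate 1, 285 without KO replicate 3, 356 without iTreg ctrl WT replicate 3 and 383 without WT replicate 1.

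With DFMO the iTreg genotypes also differed in Th1 genes. Tbx21 was 26.1-fold lower in KO (-4.71 ± 0.60, edgeR adjusted p = 9.78e-06), at 4.75 against 126 ± 33.4 CPM, and Gzmb 18.8-fold lower. The interferon-gamma gene Ifng held 534 counts in WT and 0 in KO, at least 146-fold lower against the floor of the group, a call lost with only the groups compared. Of 14 Th1 genes 9 were lower and 0 higher (11 and 1 adjusted over the list alone), such as Il12rb1 (-0.96 ± 0.11) and Cxcr3 (-2.25 ± 0.40), with a camera adjusted p of 1.56e-15 and 9.33e-05 with an estimated correlation. Pathogenic Th17 genes (5 of 12 lower, Gzmb, Tbx21, Ccl3, Ccl4 and Lag3, of which the Th1 list holds several) and non-pathogenic Th17 genes (only Cd5l of 8 lower) also held, with 7 and 5 lower adjusted over the list alone (adjusted p = 0.006 and 0.016 with an estimated correlation). The Ccl3 call was lost without iTreg DFMO WT replicate 1 (-0.89) or 3 (-0.85) or KO replicate 1 (-0.73) or 3 (-0.94), and that of Cd5l without KO replicate 2 (-2.39). Another 8 lists passed with the preset correlation only, among them ATF4 stress response, with 9 of 21 lower, such as Chac1 (13 adjusted over the list alone, adjusted p = 0.118 with an estimated correlation). The ecto-nucleotidase gene Nt5e (CD73) was 2.57-fold higher, Eng 3.26-fold and the sialyltransferase gene St6gal1 3.04-fold.

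Foxp3 was 1.51-fold higher in KO iTreg cells with DFMO (0.60 ± 0.17, edgeR adjusted p = 0.041), at 351 ± 32.1 against 232 ± 52.3 CPM. The call was lost without iTreg DFMO WT replicate 1 (0.53), 2 (0.57) or 3 (0.57) or iTreg DFMO KO replicate 1 (0.54) or 2 (0.59), with only the groups compared (0.61) and on TPM (0.69). Il17f (0.83 ± 1.41) and Odc1 (-0.02 ± 0.15) were not called. KO had 210 genes higher and 245 lower by edgeR, and 227 and 123 on TPM. The count of 455 was 727 without iTreg DFMO WT replicate 2. It was 263 without iTreg DFMO KO replicate 1, 281 without KO replicate 2, 284 without WT replicate 3 and 290 without WT replicate 1.

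The differentiations themselves were compared in ctrl libraries. In WT, Il17a was 437-fold and Il17f 241-fold higher in Th17n than in iTreg cells (8.77 ± 0.73 and 7.91 ± 0.47 by edgeR) and Il21 621-fold, in all 4 animals. Il17a held 5 counts in iTreg ctrl WT replicate 2 and 0 in the other libraries of that group. Il17f ran from 0 to 11.15 CPM in that group, so both folds are uncertain in size. Foxp3 was 29.0-fold lower, Car2 113-fold and the opioid precursor gene Penk 39.6-fold. Il23r held 225 counts in Th17n and 1 in iTreg (ratio 194, interval 34.5 to 7700). Of 19 Th17 programme genes 17 were higher and 0 lower, of 19 IL-6 and STAT3 genes 15 higher with Fos and Icos lower, and of 8 non-pathogenic Th17 genes 7 higher, such as Maf and Ahr. Of 31 DNA replication genes 29 were lower and Rfc3 higher. These 4 lists held with an estimated correlation (camera adjusted p = 0.000244, 0.00223, 0.0061 and 0.0156), and 11 more passed with the preset one only, among them glycolysis, with 18 of 21 higher (19 adjusted over the list alone, adjusted p = 0.110 with an estimated correlation). The block added the ATF4 list as lower (camera adjusted p = 0.0441, against 0.0674, and 0.537 with an estimated correlation). Kdm6b (0.12 ± 0.17) and Odc1 (0.10 ± 0.14) were not called.

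In KO ctrl libraries Il17f was 1120-fold higher in Th17n cells by edgeR, and Foxp3 47.9-fold lower. The iTreg ctrl KO libraries held 3, 0 and 3 counts of Il17f, so its fold is uncertain and cannot be ranked against that in WT. Il17a held 751 counts in Th17n and 0 in iTreg (at least 236-fold higher), and Il23r 69 and 2 (ratio 32.6, interval 8.69 to 274). Kdm6b was not called (0.16 ± 0.22). Odc1 was higher (0.46 ± 0.17), a call lost without iTreg ctrl KO replicate 1 (0.34) or 3 (0.45) or Th17n ctrl KO replicate 3 (0.36). The same 4 lists held (camera adjusted p = 0.000484 to 0.0172 with an estimated correlation), 8 passed with the preset one only, and the block added JmjC demethylases as higher (camera adjusted p = 0.0471, against 0.0615, and 0.290 with an estimated correlation). Th17n had 2188 genes higher and 2201 lower in WT, and 1950 and 1928 in KO, by edgeR. Of 3119 genes called in both, all moved the same way (1549.4 for independent lists).

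Genes that separate the cultures were then followed under DFMO, with the set for each genotype taken from ctrl libraries of the other, so that set and effect share no library. Of 855 genes at least 2-fold higher in KO Th17n than KO iTreg cells, 636 fell and 39 rose in WT Th17n cells with DFMO (median -1.08, camera p = 2.57e-27, and 1.95e-07 with an estimated correlation). Of 820 such genes from WT, 571 fell and 29 rose in KO (median -1.13, camera p = 1.20e-26, and 6.76e-07 with an estimated correlation). For genes higher in iTreg the shift depended on the fold threshold. Of 614 at least 2-fold higher, 161 rose and 107 fell in WT (median 0.14, camera p = 0.0159, and 0.0559 with an estimated correlation), and of 493, 96 rose and 65 fell in KO (median 0.03, camera p = 0.0925). Without a fold threshold 867 of 1928 rose and 272 fell in WT (median 0.283, camera p = 1.16e-11 with the preset correlation), and 1023 of 2201 rose and 226 fell in KO (median 0.357, camera p = 3.39e-17). The gene sets were also taken from 2 WT animals and the DFMO effect from the other two. Medians were then -1.09 to -0.97 for Th17n genes and 0.00 to 0.19 for iTreg genes. In iTreg cells the Th17n genes had medians of -0.57 in WT and -0.58 in KO.

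Foxp3 also set the cultures apart in their response. The DFMO effect on it was higher in WT Th17n than in WT iTreg cells (2.21 ± 0.28, edgeR adjusted p = 4.32e-06), and likewise on Nrp1 (2.29 ± 0.35), Tgm2 (2.32 ± 0.32) and the chemokine gene Ccl3 (2.65 ± 0.60). Gipr (-5.05 ± 1.19), Crispld2 (-4.01 ± 0.30) and C3 (-3.01 ± 0.58) had lower effects in Th17n. Kdm6b (0.04 ± 0.24), Odc1 (0.34 ± 0.20), Il17a (1.92 ± 3.06), Il17f (1.42 ± 1.13) and Il23r (0.02) were not called, except that Il23r was on TPM (-1.05). Values of Il17a and Il23r rest on iTreg counts near 0. No standard error is given for Il23r, since the one derived from F shrinks with a fold change near 0. Of 25 G2 and M phase genes 13 were higher, of 31 DNA replication genes 11 and of 21 ATF4 genes 10, and 9 of 19 IL-6 and STAT3 genes were lower (21, 20, 11 and 11 adjusted over the list alone). None of 9 lists held with an estimated correlation (adjusted p = 0.0532 for the IL-6 and STAT3 list, and 0.0948 for both cell cycle lists). Ribosome biogenesis passed camera at 0.0482 but not with the block (0.0604). By edgeR 372 genes were higher and 587 lower, but 926 and 225 on TPM, where the median of all genes was 0.20. The balance also turned by edgeR without iTreg DFMO WT replicate 1 (471 and 393), 3 (475 and 361) or 4 (522 and 412).

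Whether DFMO and loss of JMJD3 moved the same genes was asked in WT-based comparisons. In Th17n, 140 genes were higher under DFMO in WT and in KO ctrl (59.0 for independent lists), 12 were lower in both (23.3) and 115 moved opposite ways (90.7). The covariance of fold changes across genes was 0.0013, against 0.0405 for unchanged groups simulated on the same WT ctrl libraries. With those libraries split 2 and 2, means were 137.8 both higher (61.2 for independent lists), 11.3 both lower (16.1) and 122.8 opposite (74.8), and the covariance was -0.0403. In iTreg 191 genes were higher in both (80.5), 60 lower in both (57.0) and 156 opposite (138.8), with a covariance of 0.0585 against 0.0441 simulated. With split controls the iTreg means were 86.7 both higher (25.9 for independent lists), 16.7 both lower (13) and 62.5 opposite (38.2), and the covariance was 0.0082. Single iTreg splits varied widely, from 43 to 129 both higher, 26 to 163 opposite, and a covariance of -0.0092 to 0.035. The simulated groups had 0 KO calls in Th17n and 0.2 in iTreg by edgeR, so they give no value for the counts of shared genes.

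A set of genes recurred in these comparisons. KO and WT ctrl libraries differed in 190 genes called in both differentiations, all in the same direction, 162 of them higher in KO. Their mean log2 CPM was 5.36 ± 0.10 in Th17n ctrl WT and 6.28 ± 0.06 in ctrl KO, but 6.07 ± 0.01 in DFMO WT and 6.19 ± 0.02 in DFMO KO. In iTreg it was 4.89 ± 0.29 and 5.91 ± 0.04 in ctrl WT and KO, and 5.75 ± 0.27 and 6.09 ± 0.01 with DFMO. By edgeR, 114 of the 162 rose with DFMO in WT Th17n and 28 fell, against 42 and 45 in KO. The set was chosen on the ctrl libraries that these effects use, so it was taken again from the ctrl libraries of 2 WT animals, with the WT effects against those of the other two. In 6 such splits (55 to 193 genes), 63.2% to 86.1% of the set rose in Th17n and 52.8% to 77% in iTreg, against 20.9% to 23.6% and 13.1% to 16.6% of all genes tested. The KO libraries are too few for such a split, so part of the KO counts may come from the shared ctrl libraries. All 32 genes lower in the Th17n interaction belonged to it, and 17 of the 24 in iTreg. The interactions use the ctrl libraries on which the set was chosen, which favours such genes.

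**Figure D4:**
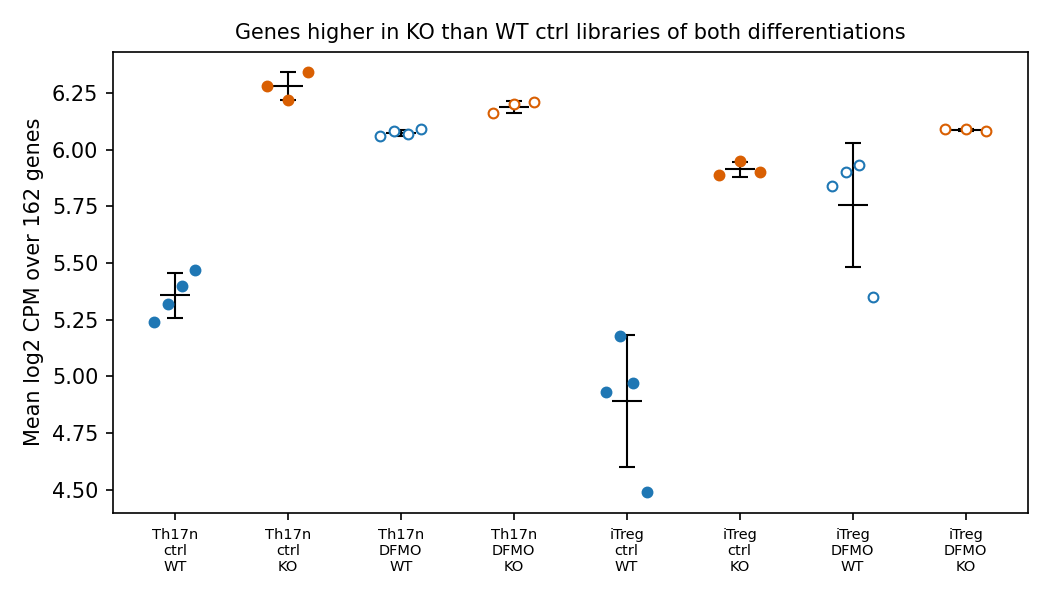
Mean log2 CPM, in each library, of the 162 genes higher in KO than WT ctrl libraries in both differentiations. WT ctrl libraries (means 5.36 and 4.89) lie below the other groups of their differentiation.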

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

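Of the tests in this part, the comparison of the shared KO genes under DFMO, used for a separate preparation of the WT ctrl libraries, and the GC corrections were chosen only after the result was seen. In 63 groups of 4 WT libraries tested for a value far from the others, 2 such values appeared, and chance gives about 1 in 20 groups. Both lay in iTreg libraries of WT animal 4. Rnf187 stood at 16.0 CPM in iTreg ctrl WT replicate 4, below the other 3 libraries. The mean log2 CPM of the 162 genes higher in KO ctrl libraries was 5.35 in iTreg DFMO WT replicate 4, also the lowest of its group.

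Genes whose DFMO effect differed between the genotypes, or between the differentiations, by edgeR's interaction test form the rest. In Th17n the DFMO effect was higher in KO for Ly6g (4.29), Plac8 (2.46), Olfr1033 (0.97) and Hmgn2 (0.49), and lower for Rnf187 (-2.39), Dusp2 (-2.19), Kctd13 (-2.06), Plbd2 (-1.77) and Micu2 (-1.62). The Olfr1033 call was lost without Th17n ctrl WT replicate 2 (0.88), ctrl KO replicate 3 (0.89), DFMO WT replicate 1 (0.85) or 3 (0.92), or DFMO KO replicate 1 (0.96) or 3 (0.94). Hmgn2 kept its call only without Th17n ctrl WT replicate 2 or 3, ctrl KO replicate 2 or DFMO KO replicate 2, and lost it without any other single library (0.42 to 0.50). In iTreg the effect was higher in KO for Sgk1 (1.57) and Ifngr1 (1.09) and lower for Rnf187 (-2.30), Kctd13 (-1.69), Rps2 (-1.63), Plbd2 (-1.54) and B3gnt2 (-1.51), and all of these but Ifngr1 lost the call with only the groups compared. Between the differentiations in WT, it was higher in Th17n for Rnf180 (2.86), Ccl3 (2.65), Tgm2 (2.32), Nrp1 (2.29) and Foxp3 (2.21), and lower for Gipr (-5.05), Crispld2 (-4.01), C3 (-3.01), Fscn1 (-2.92) and Timp1 (-2.51). Timp1 lost its call without iTreg DFMO WT replicate 1 (-1.45).

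The first pattern weighed is the set of 162 genes higher in KO than in WT ctrl libraries of both differentiations, which holds all 32 genes with a lower DFMO effect in KO Th17n and 17 of 24 in KO iTreg. The set had a median GC content of 54.6%, against 50.7% for all genes tested. A trend of expression on GC content as the whole cause is argued against, since the fitted trend was small. Its correction moved all genes by a median of 0.036 (95th percentile 0.102). The median log2 difference in Th17n was 0.848 after it (0.865 before, 144 of 162 still called). Thinning all ctrl libraries to the shallowest total gave 0.862 (130 called, against 141 with ctrl libraries alone at full depth). It leaves expected ratios between libraries unchanged, so this median could hardly move, and lower depth of KO libraries is not decided by it. Leaving out the 20 most abundant genes before scaling gave 0.871. Their shares of counts overlapped in Th17n ctrl (13.31% to 14.38% in WT, 14.11% to 14.44% in KO), so that step could move the median little. It also stays open that the WT ctrl libraries of both differentiations may have been prepared apart from the others, which the labels neither state nor exclude. With DFMO the same genes differed by a median of 0.059 in Th17n and 0.235 in iTreg, against 0.865 and 0.941 in ctrl libraries. Part of the difference thus remained, which such a preparation would not explain by itself. In iTreg 15 of the 162 were called higher, against 210 of 10985 genes tested. In Th17n 11 of the 162 were called higher, against 71 of 10985. The iTreg remainder rests in part on iTreg DFMO WT replicate 4, at a mean log2 CPM of 5.35. The other WT libraries there had 5.84, 5.9 and 5.93, against 6.08 to 6.09 in KO. An effect of JMJD3 loss that DFMO mimics in WT cells would give the same values, so these cannot be told apart, and for these genes KO against WT in ctrl libraries, DFMO in WT and the interaction tests with genotype all carry this limit.

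The second pattern is the genes called between genotypes near Kdm6b. DNA of another strain flanking the floxed allele would leave such genes close to it on chromosome 11. Within 20 Mb, 6 of 407 genes were called in both differentiations (1.47%), against 184 of 10577 elsewhere (1.74%), with a two-sided Fisher's exact p of 0.847. This argues against flanking DNA as a source of the called genes as a set. Of the 190 genes called in both differentiations, 162 belong to the first pattern, so a few flanking genes would be hard to see against them. The test does not decide single genes in that window, such as Rnf187 (2.51 in Th17n ctrl and 2.75 in iTreg ctrl) and Pdlim4 (-4.67 and -2.44), which was picked after its values were seen.

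The third pattern is the higher Ly6g in KO Th17n libraries with DFMO. Neutrophils carry Ly6g, but 5 other abundant neutrophil transcripts summed to at most 2.06% of the Ly6g CPM in those libraries, far below what such cells would bring, and the sort of naive CD4 cells would remove them. Reads shared with other Ly6 genes were not tested, and no biological explanation beyond the genotype was available.

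Other splits of the same libraries were run for each comparison, with only its groups in the fit. For KO against WT and DFMO by genotype, with 35 splits each, the share with as many genes as the real split was under 0.05. That argues against chance for each count alone, without adjustment over these comparisons. Regrouping also adds a real difference to the spread within the other splits, which can lower their counts. Real and highest other counts were 123 and 2 for DFMO by genotype in Th17n, and 4 and 0 in iTreg. KO against WT gave 416 and 6 in Th17n ctrl, 124 and 45 in Th17n DFMO, 299 and 70 in iTreg ctrl and 186 and 51 in iTreg DFMO. The 45 and 51 came from the split that set WT animals 3 and 4 with KO animal 3 against the rest. A difference shared by those animals may enter these counts. In each of these, 1 split, the real one, gave as many genes. Comparisons paired by animal in WT also had 35 splits, of which the real one alone gave as many genes, with 5765 and 1 for DFMO in Th17n, 4452 and 9 for DFMO in iTreg, 4097 and 0 for Th17n against iTreg, and 723 and 0 for DFMO by differentiation. Only 8 of those splits part all 4 animals as the real one does, which is too few for a share under 0.05, and the other 7 gave 0 genes. The splits of KO libraries were also too few, with 5378 and 0 for DFMO in Th17n, 4138 and 0 for DFMO in iTreg, and 4008 and 0 for Th17n against iTreg.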

How the results depend on the processing

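The GC corrections, the fits without both iTreg libraries of WT animal 4, the estimated correlation for the signature sets and the split ctrl libraries for the shared KO genes were tests chosen only after the result was seen. Of 19454 pairs of a named gene and an alternative, 18554 kept their direction and side of the threshold, 870 lost the call, 28 gained one and 2 reversed. Leaving out single libraries lost 581 of 8960, TPM 139 of 1135, and DESeq2 11 of 1140. The reversed values, both on TPM, were Kdm5a under DFMO in WT Th17n (0.02) and Il23r in DFMO by differentiation (-1.05). Of 233 counts of genes, 189 stayed within 1.5 times the main count.

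In DFMO by genotype in Th17n the count of 36 became 132 with no filter, 123 with only the groups compared, 57 with the replicate block, 68 with DESeq2, 8 on TPM and 62 with a GC correction and the replicate block, and 19 to 35 with 1 library left out. In iTreg the count of 27 became 146 with no filter, 4 with only the groups compared (Ifngr1 higher, Iscu, Lsm4 and Sac3d1 lower), 57 with the replicate block, 103 with DESeq2, 70 with the GC correction and block, 106 without animal 4, and 16 to 99 with 1 library left out. KO against WT in Th17n DFMO gave 230 with no filter, 45 on TPM and 28 to 129 with 1 library left out. KO against WT ran from 133 to 334 in Th17n ctrl, from 280 to 630 in iTreg ctrl and from 263 to 727 in iTreg DFMO with 1 library left out, and gave 299 and 186 in iTreg with only the groups compared. DFMO by differentiation gave 1478 with the GC correction and block. The cause was not tested for any of these.

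Of 390 list tests 125 passed camera, 22 with an estimated correlation, 151 with fry and 136 with the replicate block, which added 12 and lost 1. For DFMO and differentiation, whose libraries are paired by animal, the block changed no call of a gene or list named in the text beyond those given in the report, though counts of calls rose, in DFMO by differentiation from 959 to 1354. The labels give animal numbers no meaning across genotypes, but libraries of 1 number had a median correlation of 0.128 (0.023 to 0.189, 12 pairs, all above 0) and others -0.064 (36 pairs), and 8 of 12 KO libraries correlated best with their own number. KO replicate 3 matched WT replicate 3 or 4 best in each culture, though KO replicate 2 matched WT replicate 4 in Th17n ctrl. In Th17n ctrl WT the chi-square per degree of freedom was 5.17 for replicates 1 and 2 and 4.72 for 3 and 4. Across these pairs it was 11.17 to 18.91. In Th17n DFMO WT the parting was less clear (6.01 for 3 and 4, 5.14 for 2 and 3). This hints, from the data alone, that animals 1 and 2 shared something apart from the later numbers in both genotypes. The labels name no such batch. With the number as a replicate block KO against WT gave 451 in Th17n ctrl, 188 in Th17n DFMO, 831 in iTreg ctrl and 624 in iTreg DFMO, against 334, 112, 582 and 455, and camera added glycolysis (0.0216) and interferon-stimulated genes (0.0354) in iTreg ctrl (0.772 for both with an estimated correlation). The median of iTreg genes under DFMO in WT Th17n was 0.135 (p = 0.204) for sets at least 4-fold apart and 0.14 (p = 0.0559) with an estimated correlation. With no fold threshold it was 0.283 in WT Th17n and 0.357 in KO Th17n, and it reversed from -0.114 to 0.082 in WT iTreg and from -0.185 to 0.134 in KO iTreg. At an adjusted p under 0.1 the Th17n overlap held 28 genes lower in both and 205 opposite; the cause was not tested. With split ctrl libraries the shared KO genes had mean medians under DFMO in WT of 1.17 in Th17n and 1.21 in iTreg, against 0.91 and 1.03. Depth limits genes of few counts, which the filter removed from testing.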

Other observations

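No test in this part was chosen after its result was seen. Marker genes of other cell types were summed as a check of culture purity. The CD4 T cell markers summed to 4200 to 5310 CPM across the 8 groups. Markers of B cells (12.2 to 35), CD8 T cells (10.1 to 26.7), macrophages and monocytes (3.48 to 17.4), erythroid cells (at most 3.17), platelets (at most 3.58) and gamma delta T cells (at most 0.198) were low. The neutrophil sum was 46.7 and 105 in Th17n ctrl WT and KO and 18.2 in Th17n DFMO KO, almost all Ly6g there, and at most 0.884 in other groups. The single markers named next were picked after their values were seen. The dendritic cell sum fell from 311 to 85.2 CPM with DFMO in WT Th17n and from 354 to 93.5 in KO, and from 190 to 71.3 and 221 to 67.8 in iTreg, but single genes carried it. In WT Th17n H2-Ab1 held 291 and 69.0 CPM of it, and in WT iTreg Cd74 held 127 and 56.0 and H2-Ab1 41.1 and 4.25. The NK and innate lymphoid markers, several of which activated T cells also express, summed to 312 ± 172 CPM in iTreg ctrl WT and 219 ± 123 in iTreg DFMO WT (n = 4), against 76.9 ± 3.27 and 37.3 ± 6.10 in KO (n = 3). Nkg7 alone made up 305, 210, 74.7 and 34.7 of these sums, while Ncr1, Klrb1c, Klra8 and Gzma were at most 0.137, and the Th1 programme was also lower in KO iTreg. Of 4 Y chromosome genes only Kdm5d was tested (3.63 to 27.7 CPM), and Ddx3y, Eif2s3y and Uty had group means of at most 2.00 CPM, so the sex of the animals is not read from them.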
